A study of Castanea mollissima with 6 samples.

How the data were processed

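RNA was sequenced from 6 root samples of Castanea mollissima, the Chinese chestnut. Total RNA was extracted with a plant RNA kit and made into directional Illumina libraries, per the labels' protocols. The titles mark 3 libraries r_1m and 3 libraries r_3m; the labels do not spell out the part after the r, so both groups keep these names here. Replicate numbers were given in the order of the records and pair nothing across the groups.

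The authors deposited one table of FPKM values (fragment counts scaled to transcript length and to the mapped fragments of a library) with 33991 gene IDs and 213 columns of values, given to 2 decimals. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trimmomatic, aligned with STAR 2.7.10b and normalized to FPKM. The read counter, the genome build, the annotation and the treatment of reads that map to several genes are not given in the sources used here. Only the 6 columns whose names match the titles of the 6 root samples were used. The other 207 columns are not samples of this series and were not analysed here.

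The table pairs no gene ID with a gene name, and no table of names, genome or annotation was used. The gene lists by product name that had been fixed before the data were examined could therefore not be run. Genes are named by ID only, by the rule fixed for this case: the 2 genes higher and the 2 lower in r_3m with the largest absolute log2 fold change, among genes past the threshold whose groups did not overlap and whose mean FPKM in the higher group was at least 10. The rule also asked for the 5 genes with the highest mean FPKM in each group, which are described by rank and ID prefix (the first 4 characters of the ID). Chromosome positions were not available. Where ID distance is read below as nearness of genes, it is assumed that ID numbers follow gene order, which was not checked. Near-identical gene copies and overlapping genes could not be identified, so any gene described here may share reads with another.

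FPKM are not counts, so no count model was used. Values were transformed to log2(FPKM + 1), genes with a mean FPKM under 1 over the 6 libraries were left out, and r_3m was compared with r_1m with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over 20038 genes). A gene was called at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Measures with 1 value per library were compared with exact two-sided permutation tests in scipy 1.17.1; 3 libraries against 3 cannot give a p under 0.1, and 8 such measures were tested. Correlations between libraries were taken across genes, which are not independent replicates.

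The absolute depth of the libraries is unknown. Their relative depth was recovered from the low values, because a gene's FPKM moves in whole steps of 1 fragment, called a read here: the ratio of a low gene's values in 2 libraries piles up at the inverse ratio of their depths. Taking the deepest library, r_1m replicate 1, as 100%, the depths were 94.8% and 88.2% for r_1m replicates 2 and 3, and 64.0%, 84.4% and 88.8% for r_3m replicates 1, 2 and 3. With these depths, whole reads (within 0.2 of a read, up to 60 reads) were found for 5716 genes, among them 63.9% of the 7708 genes with a mean FPKM below 2 and a value above 0 in at least 3 libraries. The variance between libraries of a group was then compared with the counting error of those reads.

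Both procedures were tested on simulated data. In 5 simulated sets of the r_3m against r_1m comparison with 20038 genes, of which 200 were changed, the limma fit recovered 100.0% of 4-fold, 74.4% of 2-fold, 19.2% of 1.5-fold and 1.6% of 1.25-fold changes, with 0.2 false calls per set. With few changed genes the adjusted threshold is stricter than in the real comparison, so these shares are not its recovery and the 0.2 is not its number of false calls. The simulated noise was independent between genes and libraries, with a common SD for genes of like expression in a group. Effects shared by the libraries of a group, such as a batch, were not simulated. In simulated Poisson reads for 33991 genes, depths were recovered within 0.127% and 93.9% of the genes with recovered reads had the right reads.

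Before the data were examined, these alternatives were fixed: a pseudocount of 0.1, no filter or a minimum mean FPKM of 5, rescaling to a fixed total (TPM scale), median-of-ratios scaling, quantile normalization, no variance trend, a minimum of 2-fold, the 20 highest genes left out, and each library left out in turn. Group variance weights and a fit that counts the averaged r_1m libraries as 1 sample, with the spread of the r_3m libraries alone, were added after seeing the data.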

Results

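Gene expression was measured by RNA sequencing in roots of Chinese chestnut, in 3 libraries labelled r_1m and 3 labelled r_3m. The series belongs to a curation of chestnut expression data. Its root samples allow 1 comparison, of r_3m with r_1m roots, and the labels state no further question for it. The table lists 33991 genes, of which 5900 were at 0 FPKM in all 6 libraries. Relative sequencing depth, recovered from the steps of low FPKM values, ran from 88.2% to 100% of the deepest library in r_1m and from 64.0% to 88.8% in r_3m. The labels do not say whether the libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical. The run numbers in the titles form a separate consecutive block for each group, so a batch in growth, sampling or sequencing, if there was one, cannot be told apart from the group.

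Root expression profiles separated by group. Across the 20038 genes with a mean of at least 1 FPKM, Pearson correlations of log2(FPKM + 1) were 0.996 to 0.997 between the r_1m libraries, 0.974 to 0.987 between the r_3m libraries and 0.811 to 0.822 between libraries of different groups. The first principal component held 92.0% of the variance and placed the r_1m libraries between -84.25 and -84.10 and the r_3m libraries between 80.16 and 87.91. The second held 4.70% and spread the r_3m libraries from -36.13 (replicate 3) to 28.77 (replicate 1).

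On the FPKM scale, expression of about as many genes rose as fell between r_1m and r_3m. Of the 20038 genes tested, 6787 (33.9%) were higher and 6732 (33.6%) lower in r_3m, and 6519 were not called (limma, adjusted p below 0.05). FPKM are relative to the mapped fragments of each library, so this balance depends on the scaling. Calls were 7368 higher and 6277 lower on the TPM scale, and 6582 and 6887 after median-of-ratios scaling. Decreases outnumbered increases among moderate changes: 3197 genes fell and 2388 rose at least 2-fold, and 942 fell and 732 rose at least 4-fold. At least 16-fold, 139 genes were higher and 93 lower, and at least 32-fold 70 were higher and 26 lower. These counts depend on the pseudocount: at 0.1 they were 340 and 312, and 205 and 156. The median log2 fold change was 0.76 among genes called higher and -0.96 among genes called lower, and 0.02 over all tested genes. The values of both groups did not overlap for 14810 (73.9%) of the tested genes. Chance gives 10% for 3 libraries against 3 only if all 6 are independent and vary alike. Independence was not established, and the r_3m libraries varied more, so the 10% may be too low. The median standard error of a log2 fold change was 0.12. Counting the averaged r_1m libraries as 1 sample, a fit chosen after seeing the data that takes its spread from the r_3m libraries alone and assumes that r_1m varies like them, left 3408 genes higher and 3634 lower, of which 2114 and 2712 changed at least 2-fold.

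**Figure D1:**
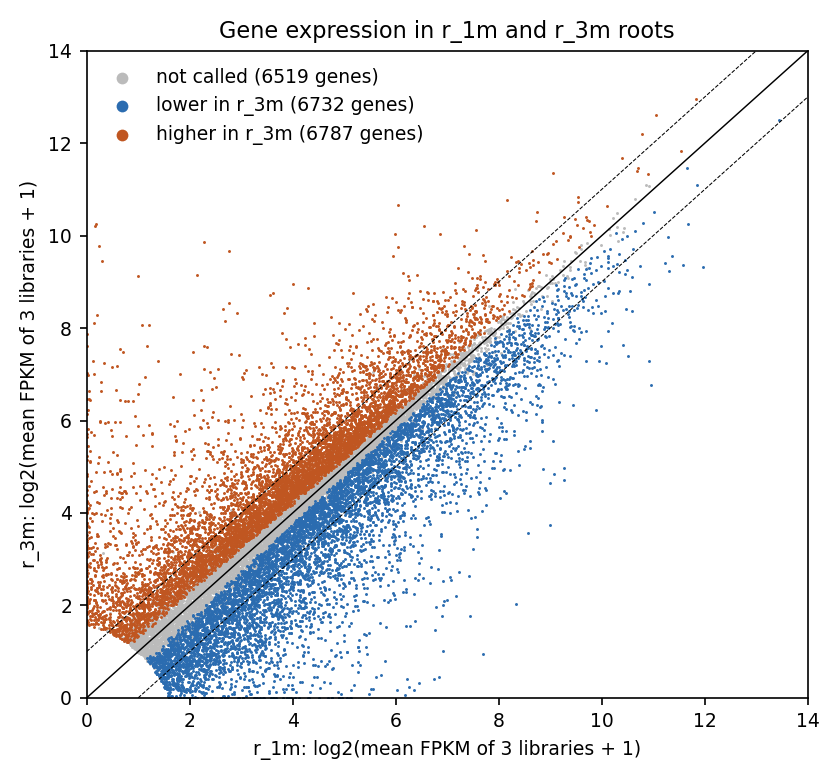
Mean expression of the 20038 tested genes in r_1m (horizontal) and r_3m (vertical), each as log2 of the mean FPKM of 3 libraries plus 1; orange points are the 6787 genes called higher in r_3m, blue the 6732 called lower and grey the 6519 not called. The solid line marks equal expression and the dashed lines a 2-fold difference on this scale; the orange points along the left edge are genes near 0 in r_1m.

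The gene with the largest increase, Cm01G00480.gene, went from values of 0.24, 0.13 and 0 FPKM in the r_1m libraries to 1175 ± 35.6 FPKM in r_3m (SD, n = 3), a log2 fold change of 10.04 ± 0.09 (SE; limma adjusted p = 1.81e-08). Cm00G00022.gene rose by 9.94 ± 0.35 on the same scale (limma adjusted p = 1.08e-06), from at most 0.29 FPKM in r_1m to 1859, 637 and 1170 FPKM in the 3 r_3m libraries. Tested genes with ID numbers close below it were also near 0 in r_1m. They too were highest in replicate 1 and lowest in replicate 2 of r_3m. The gene with the next ID number rose as well, but was highest in replicate 3. The increase of Cm00G00022.gene may therefore not be that of a single gene, and shared reads were not tested. Among the genes that fell, Cm02G02703.gene was at 206 ± 15.2 FPKM in r_1m and 0.933 ± 0.438 FPKM in r_3m (SD, n = 3 each), a log2 fold change of -6.77 ± 0.17 (SE; limma adjusted p = 3.12e-07). Cm12G00621.gene was at 114 ± 7.54 FPKM in r_1m (SD, n = 3) and at 0, 0.81 and 0.26 FPKM in the r_3m libraries, a log2 fold change of -6.44 ± 0.21 (SE; limma adjusted p = 7.07e-07). The low group of each named gene lies near the value of single reads, so these fold changes depend on the pseudocount; at a pseudocount of 0.1 they were 12.53, 12.39, -7.75 and -8.47 in the same order. The adjusted p-values above count the r_1m libraries as 3 samples, and their independence was not established. With the r_1m libraries averaged as 1 sample, the fold changes were 10.03, 9.93, -6.77 and -6.44 in that order. Averaging leaves the group means almost unchanged, so these values say nothing about whether the adjusted p-values are too small.

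**Figure D2:**
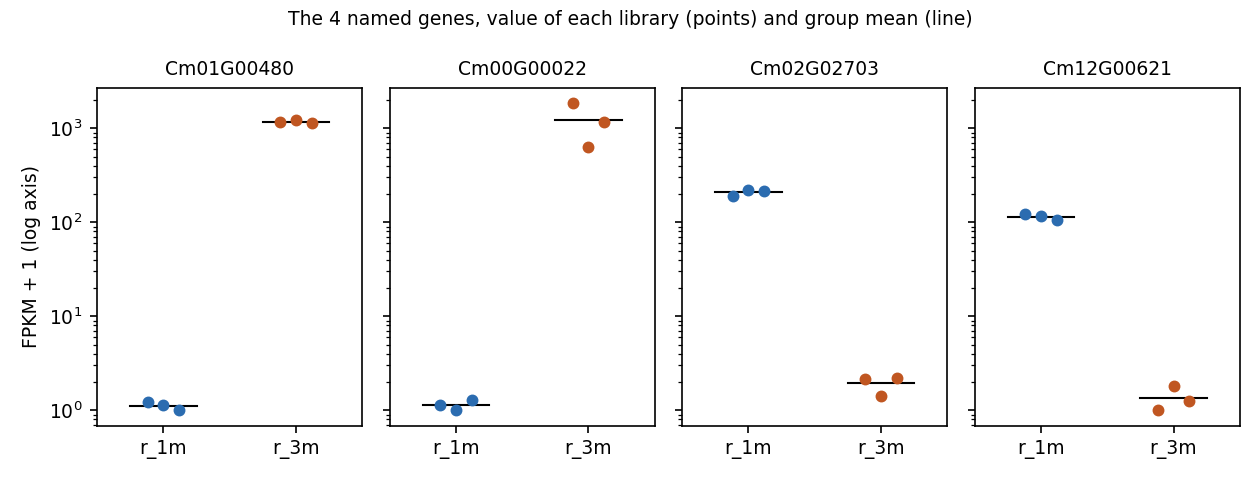
FPKM + 1 on a log axis of the 2 genes with the largest increase and the 2 with the largest decrease in r_3m, 1 point per library and a line at the mean of each group. The groups lie apart for all 4 genes, and the r_3m libraries of Cm00G00022.gene run from 637 to 1859 FPKM.

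Fewer genes had a value above 0 in the r_3m libraries than in the r_1m libraries. In r_1m 25784 ± 117 genes had a value above 0, against 24144 ± 342 in r_3m (SD, n = 3 each), and every r_3m library was below every r_1m library; at a minimum of 1 FPKM the numbers were 19651 ± 25.1 and 19274 ± 136. The exact two-sided permutation p was 0.1 for each, the smallest that 3 libraries against 3 allow. In a fit over the 6 libraries with depth as a term, r_3m had 1283 ± 16.1 (SE) fewer genes above 0 at equal depth. The fit left 3 residual degrees of freedom and took the libraries as independent, so this SE is itself uncertain. A group of 117 genes had at least 1 FPKM in every r_1m library and was listed at 0 in all r_3m libraries; 83 genes showed the opposite. At a minimum of 10 FPKM these groups held 21 and 17 genes, and their highest members averaged 33.99 FPKM in r_1m and 233.97 FPKM in r_3m.

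The most strongly expressed genes changed rank between the groups. The highest gene in r_1m, with the ID prefix Cm05, fell from 11192 ± 203 to 5768 ± 631 FPKM (SD, n = 3 each) and was the third highest in r_3m (log2 fold change -0.96 ± 0.10 SE, limma adjusted p = 1.53e-04). The second highest in r_1m, with the prefix Cm02, fell from 3991 ± 203 to 635 ± 125 FPKM and to rank 119. Those at ranks 3 and 5 in r_1m, a Cm03 and a Cm08 gene, fell from 3670 ± 110 to 2190 ± 158 and from 3255 ± 154 to 1220 ± 279 FPKM. The highest gene in r_3m, with the prefix Cm07 and at rank 4 in r_1m, rose from 3620 ± 107 to 7905 ± 991 FPKM. The gene with the next ID number was the second highest in r_3m and rose from 2132 ± 78.0 to 6220 ± 833 FPKM. A Cm11 gene rose from 1762 ± 43.4 to 4665 ± 484 FPKM and was the fourth highest in r_3m. At rank 5 in r_3m, a Cm02 gene rose from 2964 ± 84.8 to 3619 ± 344 FPKM (limma adjusted p = 0.026). A set of 49 genes was among the 100 highest of both groups. Of the 151 genes among the 100 highest of either group, 71 fell, 59 rose and 21 were not called.

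The balance of calls was also counted by expression level. Among the 202 genes with a mean of at least 500 FPKM, 107 (53.0%) fell and 57 (28.2%) rose, and their median log2 fold change was -0.36; under quantile normalization it was -0.10. In the class of 20 to 100 FPKM the calls leaned the other way, with 2505 of 6314 genes (39.7%) higher and 1935 (30.6%) lower, but not among changes of at least 2-fold, with 761 higher and 773 lower. Among the 5263 genes between 1 and 5 FPKM, 1823 (34.6%) fell and 1388 (26.4%) rose. The number of genes at or above 1000 FPKM was 74.3 ± 0.577 in r_1m and 52.0 ± 1.73 in r_3m (SD, n = 3 each, exact two-sided permutation p = 0.1). At or above 100 FPKM it went the other way, with 1889 ± 2.65 in r_1m and 1907 ± 15.7 in r_3m. Total FPKM was 918620 ± 1538 in r_1m and 881225 ± 8305 in r_3m (SD, n = 3 each, exact two-sided permutation p = 0.1 for both measures). On the TPM scale, which gives all libraries the same total, 7368 genes were called higher and 6277 lower. The 10 highest genes of a library held 4.38% ± 0.0960 of its total FPKM in r_1m and 4.83% ± 0.288 in r_3m. The share of the single highest gene was 1.22% ± 0.0202 in r_1m and 0.896% ± 0.104 in r_3m, and that of the 100 highest 16.8% ± 0.264 and 15.9% ± 0.424 (SD, n = 3 each; exact two-sided permutation p = 0.1 for each of the 3 shares).

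The r_3m libraries varied more among themselves than the r_1m libraries at every expression level. The median SD of log2 FPKM between libraries, over genes above 0 in all 6, was 0.234 in r_1m and 0.453 in r_3m for genes of 1 to 2 FPKM. It was 0.0394 and 0.171 for the 54 genes at or above 1000 FPKM. Among genes averaging at least 10 recovered reads in the group, the variance between the r_1m libraries was 0.940 times the counting error over 1900 genes, and that between the r_3m libraries was 2.695 times over 1454 genes. Simulated libraries that differed by counting error alone gave 1.01 and 1.04. Low genes of the r_1m libraries therefore differed by no more than sampling noise. The libraries were still counted as 3 samples, but their independence was not established, since the counts behind the highly expressed genes are unknown. If the r_1m libraries repeat 1 sample, the limma p-values given here may be too small.

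**Figure D3:**
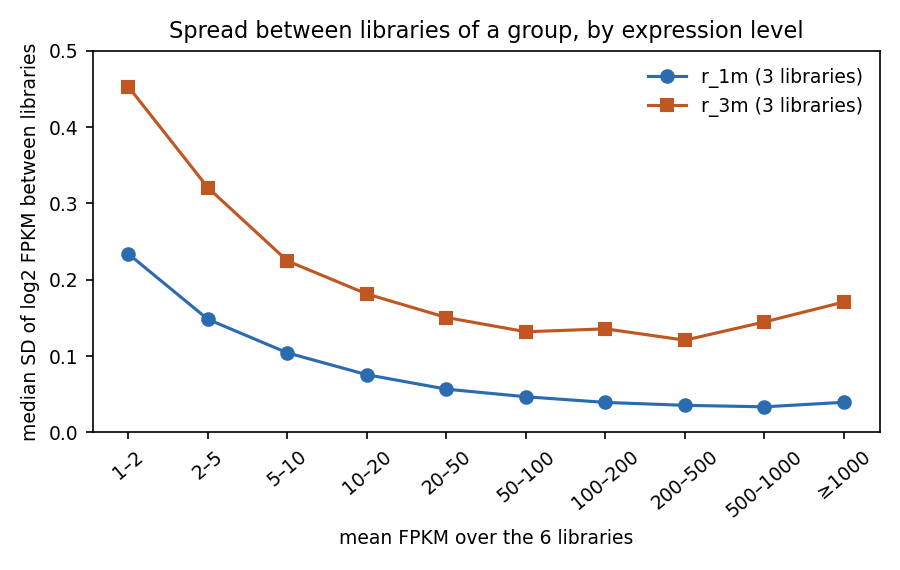
Median SD of log2 FPKM between the 3 libraries of a group (vertical) against the mean FPKM over the 6 libraries (horizontal, in classes), for r_1m (blue circles) and r_3m (orange squares). The r_3m values lie above the r_1m values in all 10 classes, from 0.453 against 0.234 in the lowest to 0.171 against 0.0394 in the highest.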

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

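No gene called under the main settings was called in the opposite direction under any of the 15 refits with at least 2 libraries in each group. The 4 named genes passed the threshold in each. All 15 reuse these same libraries, so a reversal was unlikely from the start. They test neither a batch nor the independence of the libraries. Counting the averaged r_1m libraries as 1 sample moved the calls to 3408 higher and 3634 lower; its spread comes from the r_3m libraries alone, with r_1m assumed to vary like them, so it is not counted among the 15. Requiring a 2-fold change left 2388 and 3197. The numbers of genes changed at least 2-fold stayed within 1.5 times the main counts under each of the 15, from 1785 to 2827 higher and from 2203 to 3690 lower; the lowest pair came from the filter at 5 FPKM, which tests 14775 genes. Leaving out 1 library gave 5842 to 7106 genes higher and 5769 to 7355 lower. The share of calls that were higher ran from 48.3% to 54.1% over the 15 refits and was 42.8% among calls of at least 2-fold. The median log2 fold change of the genes tested in the main fit was 0.07 on the TPM scale and -0.004 after median-of-ratios scaling. No paired analysis was possible because the labels give no replicate numbers that the groups share. The gene lists were not run. The simulated recovery of 1.5-fold changes (19.2%) holds for sets with 200 changed genes, where the adjusted threshold is stricter than with 13519 calls, and is not the recovery of this comparison. How depth limits the calling of small changes was not tested.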

Other observations

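The tests on replicate spread and on the number of expressed genes were chosen after those results were seen, and so was that at 2 IDs apart; the tests on expression level, at 10 IDs apart and on other splits of the libraries were written before their results. The likeness of fold changes of neighbouring IDs was itself not part of the analysis planned before the data were examined. Genes with neighbouring ID numbers showed a weak tendency to change together. Fold changes of genes with consecutive IDs correlated at r = 0.19 over 13713 pairs, against at most 0.025 in 1000 permutations of the genes within an ID prefix (permutation p = 0.001, the smallest these can give; adjusted p = 0.003 over 12 distances). These are correlations across genes, which are not independent replicates. The correlation was 0.087 at 2 IDs, 0.048 at 3 IDs, 0.036 at 4 IDs and 0.029 at 5 IDs apart, each above the highest of the permutations at its distance (adjusted p = 0.003 at 2 to 4 IDs and 0.0072 at 5 IDs). Runs of at least 4 consecutive IDs that all rose at least 2-fold numbered 16, where permutations averaged 1.20 and reached 6. They held 71 of the 2388 genes that rose at least 2-fold. For genes that fell there were 21 runs, with 93 of 3197 genes, where permutations averaged 3.82 and reached 12. The longest runs, of 6 genes that rose and 7 that fell, were no longer than the longest in the permutations. No ID prefix passed a test for holding more or fewer of the genes changed at least 2-fold than the others (Fisher's exact test, 26 tests, smallest adjusted p = 0.127, for Cm01 genes, of which 10.4% rose at least 2-fold against 12.2% elsewhere).

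Similar expression levels of genes with consecutive IDs are argued against as the source of this likeness: with the trend of fold change on mean expression removed, the correlation at 1 ID was 0.194. For overlap between immediately adjacent genes, the correlation at 2 IDs apart was 0.0872. It was above both the highest of the permutations (0.030) and the square of the correlation at 1 ID (0.036). The likeness therefore reached beyond pairs of consecutive IDs. This meets the prediction written against such overlap, but that prediction was written after the result was seen. The square bounds a chain of overlaps only if all neighbours are equally alike, so chains limited to some of the genes are not excluded. For reads shared between adjacent or overlapping genes in general, the correlation at 10 IDs apart was 0.0174, below the highest of the permutations (0.031); this meets the prediction written for it, but any source of short range would meet it, so it decides nothing. Reads shared between near-identical copies a few IDs apart were not tested. Gene copies in tandem that are regulated alike may give the same range. Without sequences or a statement of how reads mapping to several genes were counted, these explanations stay open, chains of overlap among them.

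The wider spread of the r_3m libraries is not explained by their lower depth alone: among genes of at least 100 FPKM the median SD of r_3m was 3.578 times that of r_1m. Nor does it rest on 1 library standing apart, since the most alike r_3m pair still had 2.165 times the spread of the least alike r_1m pair. Whether the r_1m libraries are repeat runs of 1 library cannot be told. Their low genes differed by no more than counting error. The SD of genes at or above 1000 FPKM was 3.431 times the counting error expected if 1 read is worth 0.14 FPKM, the third quartile seen at low genes. It was 1.09 times the expected counting error if a read of these genes is worth 10 times as much. The bound first set, 1.5 times, would have excluded repeat runs; the second condition was added after the 3.431 was seen, because the reads behind these genes are unknown. Pooled or technically repeated r_1m RNA and more variable r_3m plants both remain open hypotheses, which the labels cannot separate.

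The smaller number of genes above 0 in r_3m is not explained by depth as the whole cause: at equal depth the difference, r_3m minus r_1m, was -1283 genes, against -1640 without the depth term. This fit replaced a first test after its value was seen, with the same outcome: r_3m replicate 3, at 88.8% depth, had 1265 fewer genes above 0 than r_1m replicate 3, at 88.2%. A biological difference between the r_1m and r_3m roots and a batch that coincides with the groups stay open and were not tested.

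With 3 libraries in each group there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 13519 called genes and was the 1 split with as many, and the highest of the other splits gave 0 (limma, adjusted p below 0.05). Every other split mixes libraries of both groups, so a difference between the groups of whatever source, a batch included, widens its spread. The contrast therefore decides nothing about the source of the difference.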
